A study of Drosophila melanogaster with 4 samples.

How the data were processed

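The series measured binding of the CG8478 protein in chromatin of white prepupae of Drosophila melanogaster by ChIP-seq, with 2 immunoprecipitated (ChIP) and 2 input libraries, per the labels. Each library was assigned to its group and replicate from its title. The labels did not say whether the replicates came from separate collections of animals.

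The submitters' processing notes name CASAVA 1.7.0.2 and 1.7.0.3, BWA and MACS2 among the tools, without versions for BWA and MACS2, and BDGP5 as the genome build. The deposited list names MACS as the source of each region and FlyBase release 5 as its build, per the file headers. Alignment settings, the treatment of reads that match several places, the enrichment threshold and the use of the input libraries are not given in the sources used here. It is also not stated whether the ChIP libraries were pooled before calling or their lists merged. The score of each called region is the authors' deposited value from the peak caller. The file does not say whether it is a fold enrichment, a transformed p-value or another quantity, so it was used only to describe, rank and select regions within the list. Medians and their differences are given in the score's own unit, whose scale is not known. How these steps could affect the measurements cannot be worked out from 1 list: reads shared between repeat copies, a copy number of the X that differs between animals, and the caller's minimum width all act before the list is made.

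Positions were read as follows. A deposited start of 0 occurred 2 times, so starts were taken to count from 0, and 1 was added to each start. The build was never changed. No region overlapped another (0 overlaps). The table of gene names used here belongs to another assembly, Release 6 plus ISO1 MT, so its coordinates were not used. It served only for the names of histone genes and for which of them neighbour one another.

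Density per arm was the number of regions divided by the span from the first to the last called region of the arm, since the lengths of release 5 chromosomes were not used here. The design fixed before the data were examined included no test of density without a genome. The ratio of X to autosomal density with its exact conditional (Clopper-Pearson) 95% interval, and a two-sided permutation test of the mean number of region midpoints in bins of 1 Mb lying wholly within the span, with 100000 permutations, were added afterwards. Chromosome 4 held no such bin and entered the ratio only. Pairs of arms were compared over bins in the same way with Benjamini-Hochberg adjustment. Clustering was tested as planned, by the percentage of regions whose next region on the arm began within 1 kb, against 1000 random placements of the same widths within the span without overlap. Scores were compared as planned by a two-sided permutation test of the medians with 100000 permutations, with a bootstrap interval from 10000 resamples. The bootstrap, the test of widths and Fisher's exact test on the 20 highest scores were added. Chains joined regions with gaps under 5 kb. Strong regions of proximal 2L were those above the upper quartile of all scores. The placing of weak regions was described by a sum of vector strengths over 3 harmonics of the usual interval, set against 10000 random placements that kept clear of strong regions.

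The regions named were the 20 with the highest scores, a rule fixed before the data were examined. The chains and the stretch of proximal 2L were named after their values had been seen. Other settings fixed before the data were examined, and run, were the top 50% of regions by score, the 5 large arms alone, distances of 500 bp and 5 kb, and the top 10% of scores. Further ones were added after seeing the data, namely bins of 500 kb and 2 Mb, joined regions, placement within blocks of 1 Mb, random draws of as many regions as the top 50% by score, regions without the stretch of proximal 2L, the top 10% of scores for density and other thresholds for strong regions.

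Several planned analyses need a genome or annotation of release 5 and were not run: the share of regions at promoters, annotation classes, scores at promoters, divergent promoters, the gene lists fixed beforehand, known motifs, short sequence words and their relation to the score. No comparison of ChIP with input libraries was made, since the list carries no values per library.

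The tests were tried on simulated lists of 3757 regions, 200 lists for each setting. The first trial used fewer lists, and the number was raised because the shares varied too much. With no difference planted, the bin test of X density gave a p under 0.05 in 5% of lists, the spacing test in 4.5% and the score test in 6%. With a density on X planted 25% higher the mean estimated ratio was 1.25, and the 95% interval covered the planted value in 97.5% of lists. Each planted effect (that density, scores on X raised by 25%, and 20% of regions placed beside another) gave a p under 0.05 in 100% of lists. These simulations place regions independently and do not carry the clustering of the real list. They also used fewer permutations and placements than were used on the real list, and their spacing test was one-sided, not two-sided. The work used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.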

Results

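Chromatin bound by the product of the gene CG8478 was profiled in white prepupae of Drosophila melanogaster, the short immobile stage at which the larva forms the puparium and metamorphosis begins. Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was done with a rabbit polyclonal antibody raised against CG8478. The series held 2 immunoprecipitated libraries and 2 input libraries of DNA that had not been immunoprecipitated. The animals were of the strain Y cn bw sp. The values used here were 1 list of called regions, the stretches in which the authors' peak caller found enrichment. The list gave no values per library, so the read depth of the 4 libraries is unknown here, no spread between replicates could be computed, and no background value from the input libraries could be set beside a region. The p-values and intervals below cover the placing and the scores of regions within this list, not the variation between animals or libraries.

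The list held 4067 called regions, and 3757 of them (92.4%) lay on the chromosome arms 2L, 2R, 3L, 3R, X and 4. They were short stretches, with a median width of 336 bp and quartiles of 193 and 603.5 bp. Together they covered 1896 kb, of which 1794 kb lay on the 6 arms. Each region carried the peak caller's score, which is the authors' own value and whose meaning the file did not state. It is used only to describe, rank and select regions within this list, and distances between scores have no stated scale. The scores ran from 5.69 to 490.21 with a median of 19.85 and quartiles of 12 and 43.93. Wider regions had higher scores (Spearman's rho = 0.81 across the 4067 regions, permutation p = 0.0001, the smallest that 10000 permutations can give), although regions are not independent replicates. The narrowest width, 119 bp, was shared by 102 regions (2.51%), and only 6 regions were wider than 3 kb.

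The first comparison asked where in the genome the CG8478 antibody enriched DNA. The X chromosome carried more called regions for its length than the autosomes. It held 879 regions, or 39.2 per Mb between its first and last region, against 30.2 per Mb over the autosomal arms 2L, 2R, 3L, 3R and 4, a ratio of 1.30 (95% interval 1.20 to 1.40, exact and conditional on the total, counting error only). The right arm of chromosome 2 came next with 661 regions (33.8 per Mb), followed by 3L with 726 (30.3 per Mb), 3R with 830 (29.7 per Mb) and 2L with 637 (28.1 per Mb). The bases covered by regions followed the same order, with 19.3 bp per kb on X, 16.3 on 2R, 14.2 on 3L, 13.9 on 3R and 13.4 on 2L. Chromosome 4, the small and largely heterochromatic autosome, held 24 regions, which is 18.9 per Mb and 0.589 times the density of the 5 large arms (95% interval 0.377 to 0.878, counting error only).

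Density also varied along each arm. In bins of 1 Mb the X held 40.7 ± 13.5 regions (mean ± SD, n = 21 bins) and the large autosomal arms held 30.9 ± 13.4 (n = 90 bins). The means differed (two-sided permutation test, p = 0.00354), by less than 1 SD between bins. The other arms gave 34.2 ± 10.4 on 2R (19 bins), 31.5 ± 11.1 on 3L (23 bins), 29.9 ± 12.7 on 3R (26 bins) and 28.7 ± 18.1 on 2L (22 bins). The bins were chosen as the unit after the data had been seen, and neighbouring bins need not be independent. When the 5 large arms were the units, the X had the highest density, but the exact permutation p was 0.2, the smallest that 5 arms allow. None of the 10 pairs of large arms differed after Benjamini-Hochberg adjustment of the permutation test (0 of 10 with an adjusted p under 0.05). The X against 2L, 3L and 3R each gave an adjusted p of 0.0637 (unadjusted permutation p = 0.0168, 0.0191 and 0.00814), the X against 2R gave 0.26, and pairs without the X gave 0.447 or more. Among the top 10% of regions by score the ratio was 1.26 and its interval, 0.976 to 1.62, included 1 (permutation p = 0.127).

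**Figure D1:**
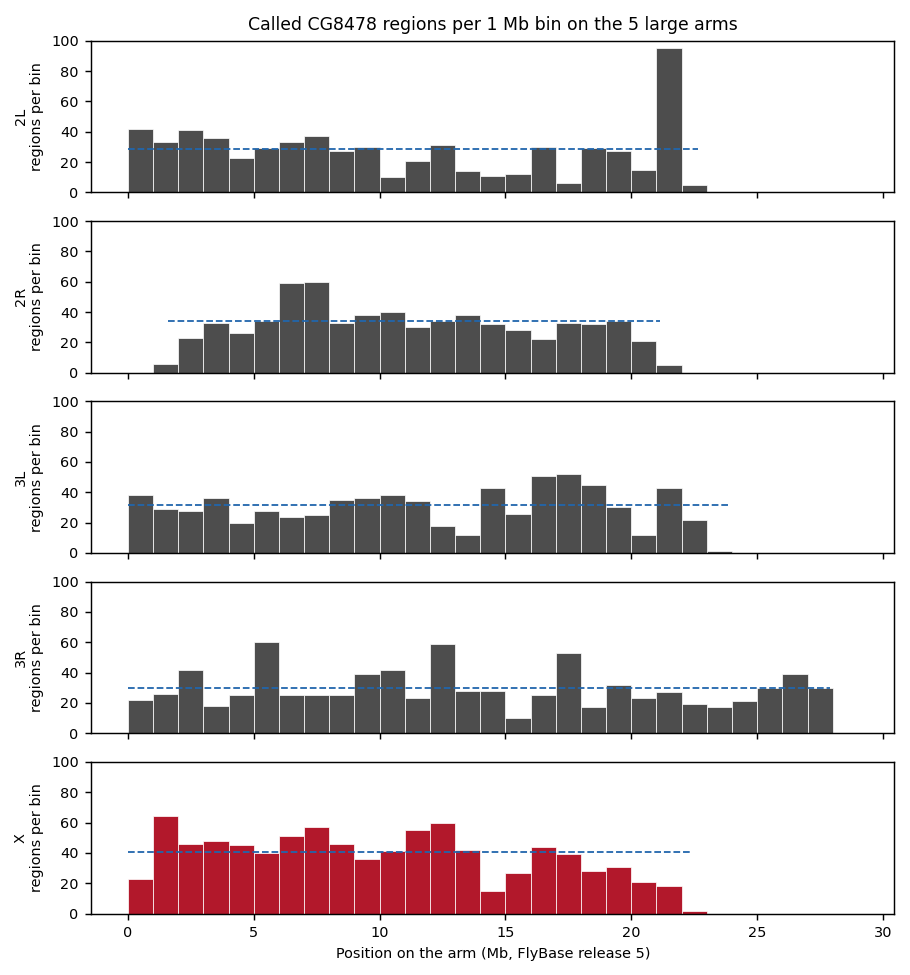
Called regions per 1 Mb bin (vertical axis, number of region midpoints) along the 5 large arms (horizontal axis, position in Mb, FlyBase release 5), with X in red, the autosomal arms in grey and a dashed line at each arm's mean over the bins that lie wholly between its first and last region. The X mean is 40.7 regions per bin, the autosomal arms range from 28.7 to 34.2, and 1 bin of 2L reaches 95.

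The second comparison asked whether called regions cluster along the arms. They did. Of the 3757 regions on the arms, 866 (23.1%) had the next region within 1 kb, against 3.23% ± 0.28 (mean ± SD of 1000 random placements of the same regions within their arm) and at most 4.13% in any placement (two-sided p by permutation of positions = 0.002, the smallest that 1000 placements allow). On each arm the observed share lay above random placement, whose means ran from 1.67% on chromosome 4 to 3.92% on X. The observed share ran from 21.1% on 3L to 24.3% on 2L among the large arms. On chromosome 4 it was 25%, from 6 of 24 regions. The ratio to random placement fell with distance, from 10.8 within 0.5 kb (17.7% of regions against a random mean of 1.64%) and 7.13 within 1 kb to 2.65 within 5 kb (40.1% against 15.1%), 1.80 within 10 kb (50.2% against 28.0%) and 1.01 within 50 kb (81.2% against 80.3%, permutation p = 0.00999). These shares are cumulative, so the ratio has less room to exceed 1 as the random share grows. Its fall therefore does not by itself give the range of the clustering. Among the top 50% of regions by score, 163 of 1886 (8.64%) had the next one within 1 kb, against a random mean of 1.64%. Taking fewer regions lowers this share by itself: 1000 random draws of 1886 regions from the list gave 12.8% ± 0.61 (mean ± SD, lowest 10.2%), so the share among the higher scores lay below that of random draws (two-sided permutation p = 0.002, the smallest that 1000 draws allow). Regions less than 1 kb apart can be parts of 1 enriched stretch that the caller divided. With such regions joined, 639 of 2891 sites (22.1%) still had the next site within 5 kb, against 11.9% ± 0.58 for random placement (highest 13.7%). Joining and the random draws were chosen after the data had been seen.

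**Figure D2:**
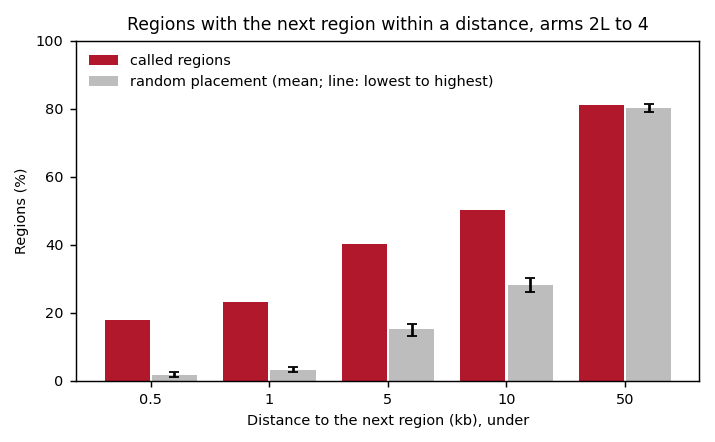
Percentage of called regions on the 6 arms whose next region lies within 0.5, 1, 5, 10 or 50 kb (red bars), beside the mean of 1000 random placements within the arm (grey bars, with lines from the lowest to the highest placement). At 1 kb the values are 23.1% and 3.23%, and at 50 kb they are 81.2% and 80.3%.

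When regions with gaps under 5 kb were chained, 98 chains held at least 5 regions each, 697 regions in all (18.6% of those on the arms). Random placement gave 1.84 such chains on average and at most 8, and its longest chain had 8 regions. The longest chains in the data lay in proximal 2L, at 21451200 to 21541594 with 66 regions and at 21417054 to 21440701 with 17. Outside this stretch the chains with most regions were at 3R 5902435 to 5919488 (14 regions), 2L 1643547 to 1670178 (12), 3R 17430959 to 17445752 (12) and X 6747544 to 6763061 (12). These coordinates and all others are in FlyBase release 5. Within each of 5 classes of gap, no rank correlation between the scores of adjacent regions was detected. Spearman's rho lay between -0.05 and 0.02, with 866 pairs under 1 kb apart and a lowest adjusted permutation p of 0.69. A correlation within a class cannot show whether scores differ between classes. Pairs under 1 kb apart had a median higher score of 29.3 and a median lower score of 11.3. In the classes with wider gaps these medians ran from 36.78 to 40.15 and from 12.8 to 14.2. That difference was not tested. Among the higher-scoring regions, a next one within 1 kb was also rarer than in random draws of as many regions, as given above.

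The third comparison asked whether regions on the X were stronger as well as denser. Their scores did not differ detectably from those on the autosomes. The median score was 19.98 on X and 19.76 on the autosomes, a difference of 0.22 (95% bootstrap interval -1.12 to 2.45, two-sided permutation p = 0.716). The top 10% of scores took in 82 X regions (9.33%) and 276 autosomal regions (9.59%; Fisher's exact p = 0.844). Median widths were 363 bp and 337.5 bp (permutation p = 0.0873). Over the 4 tests of X regions against autosomal ones, the last being the count of the highest scores given next, no Benjamini-Hochberg adjusted p was under 0.05.

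The 20 regions with the highest scores were taken by a rule fixed before the data were examined. The strongest lay at X 8544644 to 8545683 with a score of 490.21, at 3L 377163 to 378659 with 458.54 and at 2R 15993698 to 15994481 with 430.24. They were followed by X 17662077 to 17662880 (387.34), X 4320613 to 4321328 (367.96), 2L 7827804 to 7829377 (356.08), 3R 677992 to 678772 (342.49) and 3L 14124377 to 14125410 (333.67). The remaining 12 scored between 297.87 and 326.16. On the X these were 2016599 to 2018181, 19471989 to 19473786, 5487853 to 5488361, 4305227 to 4306105, 5454337 to 5455108 and 7954028 to 7955520. On the autosomes they were 2L 22024358 to 22024890, 2R 7415196 to 7416476, 3R 9700442 to 9701320, 3L 10849150 to 10851028, 2L 16485523 to 16487238 and 3R 6439860 to 6441012. All 20 were between 509 and 1879 bp wide. The genes at these positions were not analysed here, since no annotation of release 5 was used. The X held 9 of the 20, against 23.3% of the other regions on the arms (Fisher's exact p = 0.0318), which did not pass the adjustment over the 4 tests (adjusted p = 0.127).

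The stretch of proximal 2L with the longest chains stood apart from the rest of the arm. Between 21417054 and 21541594, over 124.5 kb, it held 83 called regions, 13.03% of those on 2L, at 666 per Mb against 24.6 per Mb on the rest of the arm. Strong and weak regions were interspersed there. The 23 regions in the top 25% of scores had a median score of 104.5 (range 48.61 to 155.97) and a median width of 1021 bp (681 to 1338 bp). The other 60 scored between 6.06 and 20.58 with a median width of 155.5 bp. Midpoints of consecutive strong regions were 5.09 ± 0.39 kb apart in 21 of the 22 intervals (4.65 to 6.63 kb), and the remaining interval was 14.3 kb. The coefficient of variation of the 22 intervals was 0.362, whereas 789 other runs of 23 consecutive strong regions on the large arms, which overlap one another, had 0.737 or more. The stretch and the rule for strong regions were chosen after the data had been seen, so these values describe the stretch and are not a test of it. A scan for a period between 1.5 and 12 kb over all 85 regions of a slightly wider window, made first, gave no period beyond chance (highest vector strength 0.28, permutation p = 0.219 from 200 draws of random positions). The 23 strong regions alone had their highest vector strength, 0.88, at 5 kb, and the 60 weak ones theirs, 0.40, at 2.49 kb, but these sets were picked with the spacing in view and no p is given for them.

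**Figure D3:**
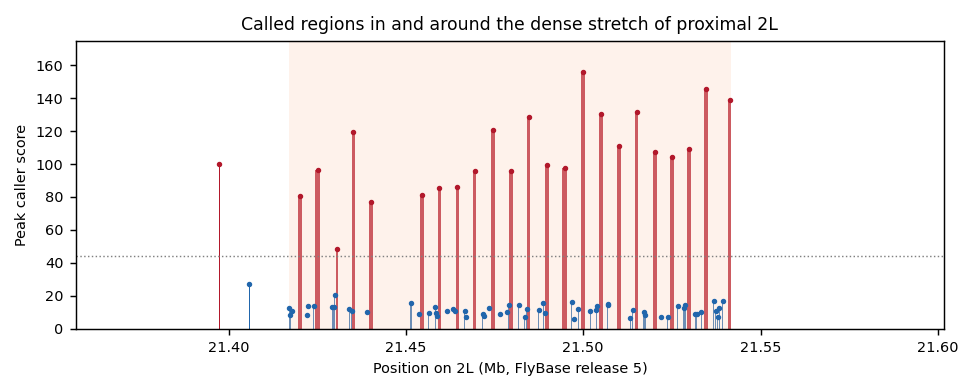
Called regions in proximal 2L by position (horizontal axis, Mb, FlyBase release 5) and peak caller score (vertical axis), with the 124.5 kb stretch shaded, regions above the upper quartile of 43.93 (dotted line) in red and the others in blue. The 23 strong regions of the stretch lie at intervals of about 5.09 kb with 1 interval of 14.3 kb, and the 60 weak ones score at most 20.58.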

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

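The tests in this part were all chosen after the data had been seen. A signal appeared in sequence that the comparisons between arms left out. Uextra, a set of unplaced scaffolds of release 5, carried 291 called regions, 7.16% of the list (Wilson 95% interval 6.40 to 7.99%, counting error only). For its length this was no excess: Uextra held 10.3 regions per Mb between its first and last region, against 32.1 on the 5 large arms. Scores on Uextra reached 217.56, and their median was 18.22 against 19.93 on the arms (permutation p = 0.237). The median width was 242 bp against 343 bp (permutation p = 4e-05). The regions of Uextra were the narrower ones in 8 of 10 score classes of equal size, with ratios of the median widths from 0.585 to 1.02. Weak calls near the caller's threshold are a possible explanation, and these would place fewer Uextra regions among the highest scores. As the whole explanation they are argued against, since the top 10% of scores took in 15.8% of Uextra regions (46 of 291, Wilson interval 12.1 to 20.4%) against 9.53% on the arms (Fisher's exact p = 0.0011, adjusted over 2 thresholds 0.0022), and the top 25% took in 26.8% (78 of 291, Wilson interval 22.04 to 32.17%) against 24.8% (p = 0.440). The Fisher p-values and the intervals count each region as independent, which regions on copies of the same sequence would not be. Copies of sequence, within Uextra or placed elsewhere, were not analysed here, and no biological explanation was tested.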

How the results depend on the processing

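The density ratio itself and those alternatives not listed as planned were chosen after the data had been seen. The ratio of X to autosomal density kept its direction and a permutation p under 0.05 in 6 of 7 alternatives (ratios 1.29 to 1.34). In the seventh, the top 10% by score, it was 1.26 with an interval from 0.976 to 1.62 and a permutation p of 0.127, over fewer regions. Bins of 500 kb and 2 Mb cannot change the ratio and vary only the permutation test (p = 0.00168 and 0.0268). The 5 large arms alone leave out only the 24 regions of chromosome 4. Clustering kept its direction and stayed beyond the random placements in 6 of 6 alternatives, although the excess over random placement at 1 kb was 7.0 percentage points in the top 50% by score and 19.8 in the whole list. The median score difference between X and autosomes was 0.05 without the stretch of proximal 2L. The difference in the share of the top 10% of scores had the opposite sign, -0.26 percentage points (Fisher's exact p = 0.844), with neither past the threshold. The cause was not tested. For proximal 2L, the top 33.3% of scores selected the same 23 strong regions, so it tested nothing further, and the top 20% selected 22 and gave an interval coefficient of variation of 0.391. No paired analysis was possible because the list holds no values per library, and for the same reason leaving out each replicate was not run. Alternatives that need a genome or annotation of release 5 were not run. The unknown depth limits what the list can say of weak regions.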

Other observations

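The tests in this part were chosen after the data had been seen, except that the top 50% by score was a setting fixed before the data were examined, here applied to a density ratio that was added afterwards. The left ends of 2 arms as the build has them fell within the widest regions of the list. On 3L the region from 1 to 20044 scored 128.15, and on 2L the region from 1 to 6119 scored 248.07, whereas the next widest, 2L 2195965 to 2200651, measured 4687 bp. Among the 20 highest scores, 2 pairs lay within 50 kb of each other, both on X, with gaps of 14.5 kb (4305227 to 4306105 and 4320613 to 4321328) and 32.7 kb (5454337 to 5455108 and 5487853 to 5488361). As many pairs were found in 4.7% of 1000 random draws of 20 regions from the arms. The draws did not keep the arms of the 20 highest, 9 of which lay on X. The 4.7% therefore does not separate pairing from the share of X. Regions in the top 10% of scores had a neighbour within 1 kb about as often as others, at 34.6% (124 of 358) against 38.7% (1317 of 3399; Fisher's exact p = 0.137). The heterochromatic sequences 2RHet, 3LHet and 3RHet together held 4 regions, with scores from 7.91 to 143.19.

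The strong regions of proximal 2L recurred at an interval of 5.09 ± 0.39 kb. The weak regions were unevenly placed between the strong ones. Of the 60, 28 lay 500 to 1500 bp and 24 lay 2500 to 3500 bp before the next strong midpoint. Their summed vector strength was 1.31 against 0.677 for random places (permutation p = 0.0001, the smallest that 10000 placements can give). The windows, the interval and the strong set were chosen with the positions in view, and the p treats the weak regions as independent. The p therefore describes the stretch and is not a separate test of the pattern. Whether the caller split 1 broad domain cannot be decided from these values. A domain over repeated units could be divided at the same place in each unit. Reads shared between near-identical repeat copies would give like ranks, and the SD of the 23 scores' percentile ranks in the list was 3.95, below the 4.98 or more of the 789 other runs; identical copies bound alike could give the same value. A hypothesis is that the stretch may be the tandem histone gene cluster, whose name was among the lists fixed beforehand: the gene table of Release 6 plus ISO1 MT holds 111 genes named as copies of His1 (23), His2A (20), His2B (23), His3 (23) or His4 (22), all on 2L, beside 23 strong regions, and histone variant genes under other names were not counted. They form 1 unbroken run once the 24 small RNA and pseudogene entries among them are passed over, and 24 runs otherwise, but the table and the list belong to different assemblies and the 14.3 kb interval spans 2.83 usual ones, so the numbers do not decide it and the positions were not compared.

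The X carried 1.30 times as many called regions per Mb as the autosomes. The permutation p-values that follow take bins of 1 Mb as units, and neighbouring bins of an arm need not be independent. With the 5 large arms as units the exact permutation p was 0.2, the smallest that 5 arms allow. None of the 10 pairs of large arms differed after adjustment. The values below therefore bear on how calls were made on this X, not on whether X differs from arms in general. Weak calls near the caller's threshold are argued against as the whole explanation, since the top 50% by score gave 1.34 (permutation p over bins = 0.00087). Its interval, 1.20 to 1.49, covers counting error only. However, the top 10% gave 1.26 with an interval that included 1. Single sites split into several calls are argued against by the ratio of joined sites, 1.30 (permutation p over bins = 0.00061). Its interval, 1.19 to 1.42, covers counting error only, with 676 sites on X and 2215 on autosomes. A few dense stretches are argued against by the median bins, 42 on X and 29.5 on autosomes, a difference of 12.5 (permutation p = 0.00032), with 16 of 21 X bins above the autosomal median. The copy number of X in the libraries, mappability and gene density remain open, as they were not analysed here, and no biological explanation was tested.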
